A study of Gallus gallus with 4 samples.

How the data were processed

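RNA from bisected chick optic tecta was hybridised to 4 two-colour arrays of 45220 spots, 42034 of them gene probes. The tecta came from embryos at stages HH30, HH35 and HH37, and 60 pieces were pooled per channel, per the labels' protocols. Each of the 4 groups, anteroposterior at HH35 and HH37 and mediolateral at HH30 and HH35, is 1 array, and that number limits the precision.

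The deposited spot tables give the intensity of each spot in linear units, not normalised, per the file headers, together with a signal-to-noise score and the percent of saturated pixels per spot, also deposited. The authors used Agilent Feature Extraction, per the submitters' processing notes, but the columns of the spot tables are those of GenePix. The scanner settings are not given in the sources used here. The authors' deposited table gives a ratio per probe and array and the same ratio as a fold change, with normalisation steps not given in the sources used here. The deposited value table of the series is the log2 of that ratio. Both run against Cy5 over Cy3 on all 4 arrays, so the value table was turned to Cy5 over Cy3, after which it correlated across 41824 probes with the ratios computed here with r between 0.724 and 0.848. Its median was -0.13 on the anteroposterior array at HH37 after turning.

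From the spot tables, background was corrected with the normexp method at an offset of 50 on the mean foreground and median background of each spot, and log2 ratios of Cy5 over Cy3 were normalised by loess at a span of 0.3 with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The columns planned for were those of Feature Extraction, and the GenePix columns took their place. A probe was taken as measured where the mean foreground exceeded the median background by more than 2.6 SD of the background in at least 1 channel and the spot was not marked as not found. That limit replaced the planned one once the file format was known and before ratios were computed. A ratio with 1 channel under the limit is given as a lower bound for the fold, while figures, list medians and limma use it as computed. That bound applies to the background correction and normalisation used, and some alternatives gave smaller ratios. Spots marked not found numbered 2188, 3479, 2654 and 2737. Saturated spots were kept. Each gene is represented by its brightest probe.

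Gene symbols came from the names and accessions in the files and from a table of chicken genes of assembly GRCg7b, used for names only since the files name no build. This named 9901 probes of 8515 genes, and 31727 features kept no symbol. Names and accessions disagreed for 42 probes, which were left unnamed. EN1, EFNA6, DLX6 and NKX6-1 were named from probe descriptions, the last pair after the files were seen.

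On each array, features with a ratio of at least 2-fold were counted with no test. Over both stages of an axis, 30306 features measured on at least 2 arrays were fitted in limma with 1 coefficient per axis and 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Stage differences are part of the residual of that fit. The contrast of the axes came from the same fit. Tested on simulated data of 30306 genes for the anteroposterior comparison, the fit recovered 90% of 100 genes changed by 1 on the log2 scale and 100% of 100 changed by 2, with 7 false calls. The simulated noise was independent between genes and arrays and held no dye effect. The 7 false calls therefore do not measure the error rate among calls on the real arrays. For each of 35 gene lists, fixed before the data were examined, the median ratio was ranked among 10000 random lists matched on brightness in 20 bins, or 2000 in the alternatives, where at least 3 members were measured. Percentiles in the outer 2.5% at either end were taken as outside, a limit chosen after the values were seen. Medians fell outside in 47 of 136 cases, where 6.8 would for lists of genes drawn at random. Members of a list may vary together and the arrays correlate, so the excess over 6.8 does not exclude chance.

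The genes named were chosen by a rule written before the data were examined. It took, per axis, the 10 highest and 10 lowest genes with a symbol by the smaller ratio of both stages, per array the 5 highest and 5 lowest, per axis the 4 with the greatest rise and the 4 with the greatest fall between stages, all measured Eph receptors and ephrins, a set of fixed patterning genes, and up to 4 members of each other list, 251 genes in all. Some of these genes are not reported here. Alternatives covered background correction, loess, the value table, the filter on dim probes, the choice of probe, thresholds, a dye estimate, the variance model, array weights and leaving out each array. A filter on negative controls, a filter on the signal-to-noise score above 3 and the median of spot pixels were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.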

Results

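Gene expression was compared between opposite sides of the optic tectum of chick embryos, the midbrain structure that receives the axons of the retina, on 4 two-colour microarrays. The anteroposterior axis was measured at Hamburger-Hamilton stages HH35 and HH37, and the mediolateral axis at HH30 and HH35. Each array compared a pool of 60 pieces of bisected tecta labelled with Cy5 with a pool of 60 opposite pieces labelled with Cy3. Each axis and stage therefore had 1 array, with no biological replicate and no dye swap, per the series' design text, so no difference on a single array has a replicate check. The median foreground intensity in the Cy5 and Cy3 channels was 194 and 229 for the anteroposterior array at HH35, 99 and 107 at HH37, 135 and 130 for the mediolateral array at HH30 and 149 and 140 at HH35. Of 42034 gene probes, 79.5%, 63.2%, 70.1% and 70.9% stood well above background in at least 1 channel of these arrays, in the same order. In Cy5 the share was 59.5%, 41.2%, 50.7% and 53.0%, against 79.4%, 63.2%, 70.0% and 70.8% in Cy3. The limit was thus missed more often in Cy5 on every array. The median SD of the log2 ratio among repeated control spots lay between 0.11 and 0.13, which measures the spread of spots within an array only. Ratios are log2 of Cy5 over Cy3. On the anteroposterior arrays this is posterior over anterior, by the dye labels and by the authors' deposited table alike.

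Along the anteroposterior axis at HH35, the 5 genes with a symbol furthest to either side are given first. EPHA3 and EPHA7, receptor tyrosine kinases that bind ephrin-A ligands, had log2 ratios of -2.46 and -2.38, 5.51-fold and 5.20-fold higher in the anterior pool. ALDH1A2, an enzyme of retinoic acid synthesis, stood at -2.22 and the cell adhesion gene PCDH10 at -1.47, also anterior. SLC36A4, ranked here by its computed ratio, was at least 2.68-fold higher anteriorly, its posterior channel being not well above background. On the posterior side were PAX2, a paired-box gene of the midbrain-hindbrain boundary, at 3.0, gastrin-releasing peptide GRP at 2.49, the axon guidance gene NTN1 at 1.75, the homeobox gene EN1 at 1.69 and the secreted Wnt modulator SFRP1 at 1.60. The EN1 value came from a probe named through its description in the files, and the other NTN1 probe gave -0.02. In all, 250 of 31891 measured genes and unnamed features differed at least 2-fold, 201 higher in the anterior pool and 49 higher in the posterior pool. With median centring in place of loess the split was 670 to 30.

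At HH37 the 5 genes with a symbol furthest to the anterior side were MAP1B, NR2F2, SPTBN1, EPHA3 and HBBA. MAP1B, a microtubule-associated protein of growing axons, stood at -2.17 and the spectrin gene SPTBN1 at -1.75. NR2F2, an orphan nuclear receptor, was at -1.75, EPHA3 at -1.71 and the haemoglobin gene HBBA at -1.68. The 5 highest named genes on the posterior side were TUBA5 at 1.24, PHC1 at 1.20, PDZK1P1 at 1.11, SNRNP40 at 1.05 and the prefoldin subunit PFDN1 at 0.86. PHC1 and SNRNP40 turned to -0.69 and -0.32 in the series' value table. The authors' deposited table gave PDZK1P1 a posterior over anterior ratio of only 1.1 at HH37, against 2.63 for TUBA5 and 3.66 for PFDN1. EN1, at 1.69 at HH35, was at 0.02 at HH37. At this stage 475 of 25347 measured features differed at least 2-fold, 450 higher anteriorly and 25 posteriorly. In the value table the split was 1654 to 582. This was the dimmest array.

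Across both stages, genes that were higher in the anterior pool outnumbered those higher in the posterior pool. EPHA3 had a mean log2 ratio of -2.08 ± 0.20 (SE, limma moderated test, adjusted p = 0.00764), and MAP1B of -1.66 ± 0.22 (adjusted p = 0.0174 by limma). PPP3CA, the catalytic subunit of calcineurin, stood at -1.35, the neurofilament gene NEFM at -1.34, ELMOD1 at -1.17, the synaptic vesicle calcium sensor SYT1 at -1.17, the dynein subunit DYNC1I1 at -0.99 and the histone gene H3F3B at -0.93, all past the threshold of adjusted p 0.05 in limma. NR2F2, at -1.34, did not pass (adjusted p = 0.0529 by limma). On the posterior side 5 genes with a symbol passed. These were DIO3, the enzyme that inactivates thyroid hormone, at 1.03, PFDN1 at 0.70, the zinc transporter SLC30A2 at 0.68, MSI1, an RNA-binding protein of neural progenitors, at 0.66, and the neurogenic transcription factor NEUROD4, whose anterior channel was not well above background at HH35 and whose log2 ratio was 0.58 at HH37. CRYBB2 at 0.70, TMEM104 at 0.55, OVALY at 0.51, EPGN at 0.51 and C17orf78 at 0.51 were higher posteriorly at both stages and did not pass. Limma called 833 of 30306 features, 791 higher anteriorly and 42 posteriorly, of which 262 and 5 had a symbol. The 2 stages of an axis served as its 2 observations, and a dye effect of a gene cannot be told from a difference between pools in this test. The count was 0 with plain background subtraction, 0 in the value table (5400 at unadjusted p under 0.05), 1 with an intensity trend and robust variance, 4290 with median centring, and 1470 without the HH35 array. Of the 38 named genes that passed, all 38 kept their sign under each of these settings. They were picked by this test on the same arrays, so the kept sign is no further support. With plain subtraction, the value table, or trend and robust variance, 0 of the 38 were called again. Of the 833 features 453, and of the 38 genes 18, lay on the same side on all 4 arrays. The mediolateral mean had the sign of the anteroposterior mean for 661 of the 833 features and 28 of the 38 genes. For PTPRO, FGFR3, LHFPL1, TGFB2 and LEF1 the mediolateral mean was at least 50% of the anteroposterior mean.

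**Figure D1:**
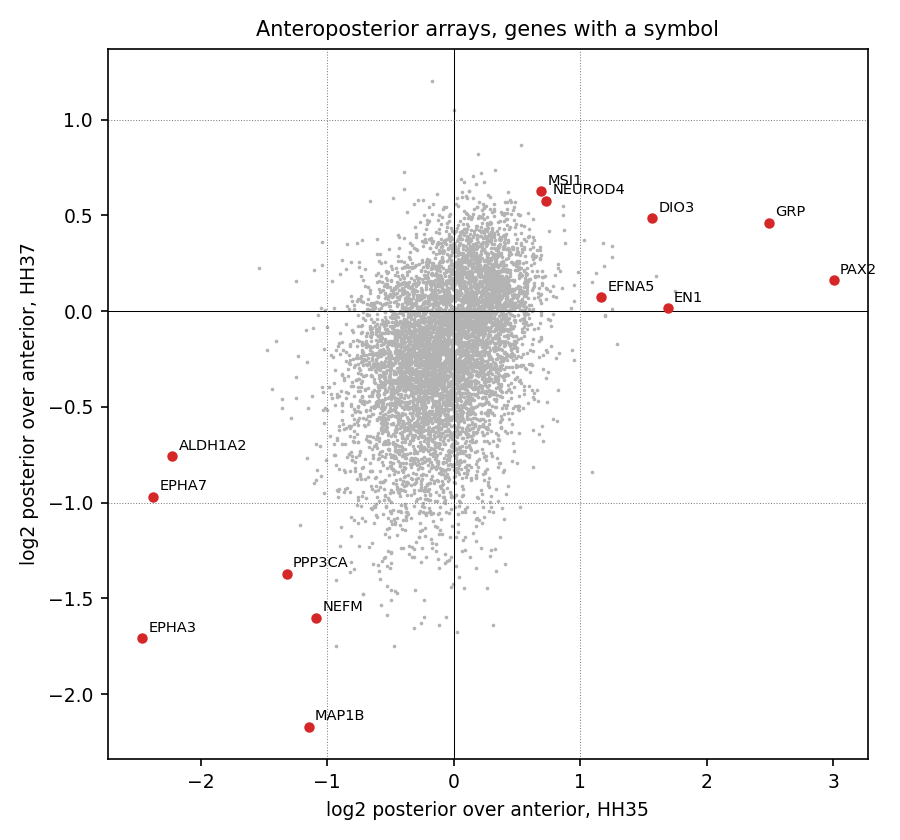
Log2 ratio of posterior over anterior tectum at HH35 (x axis) and at HH37 (y axis), 1 array each. Each grey point is a gene with a symbol that stood well above background on both arrays, red points are labelled genes, and dotted lines mark a 2-fold difference. EPHA3 lies at -2.46 and -1.71. PAX2 lies at 3.0 at HH35, and its height at HH37 rests on a posterior channel not well above background.

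At a threshold of 2-fold, 13 features were higher anteriorly at both stages, where independent lists would share 3.46, and 1 was higher posteriorly, where they would share 0.028. EPHA3, PPP3CA, MAP1B, ELMOD1 and NEFM were the 5 of them with a symbol. A single feature, LOC419390, stood on the posterior side, at 1.15 and 1.31. It was chosen for naming after its values were seen. The ratio had the same sign at both stages for 67.7% of the 24284 features measured on both arrays. In the value table the shared 2-fold features were 113 anterior and 22 posterior. With the other axis subtracted as a dye estimate they were 25 and 14.

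EphA receptors stood mostly on the anterior side of this axis. Of 5 measured EphA receptors, 3 were higher anteriorly by limma over all genes and 4 adjusted over the list alone. EPHA4 stood at -0.75 and -0.75 at the 2 stages, EPHA5 at 0.29 and -0.28, and EPHA6 at -0.74 at HH35. At HH37 the posterior channels of EPHA7 and EPHA6 were not well above background, so they were at least 1.96-fold and 1.66-fold higher anteriorly. The list's median of -0.75 was at percentile 0.08 of 10000 matched random lists at HH35, and that of -0.75 at percentile 2.02 at HH37, where 6 of 7 alternatives left it outside the limits of random lists. The 3 measured ephrin-A ligands had medians of 0.68 at HH35 (percentile 99.92) and 0.22 at HH37 (percentile 96.96, inside the limits), the latter turning to -0.0018 with median centring, with 0 past the test over all genes and 2 adjusted over the list alone. EFNA5 was at 1.16 at HH35, its other probe giving 0.09. At HH37 its posterior channel was not well above background, so no size is given. Its computed ratio there was still above 0, as for all 3 members. EFNA2 was at 0.42 and 0.22. EFNA6, named through its description, was at least 1.60-fold higher posteriorly at HH35, its anterior channel being not well above background, and at 0.32 at HH37. It is the middle member of the list at HH35. The list was also higher in the Cy5 pool on the mediolateral arrays, at 0.22 at HH30 (percentile 90.56) and 0.41 at HH35 (percentile 99.63), with 2 members past the test adjusted over the list alone, and the contrast of the axes had a median of 0.0879 with 0 called. EFNA2 was at 0.22 and 0.58 there, EFNA6 at 0.41 and 0.41, and EFNA5 at -0.07 and 0.09. A dye effect of EFNA2 and EFNA6 is thus not told from a posterior excess. Of the 4 EphB receptors, 0 passed over all genes. EPHB1 was at -0.07 at HH35 and -1.32 at HH37. EFNB1 stood at 0.48 and 0.04, and EFNB2 at -0.10 at HH35. EPHA1 was not well above background on any array. Of the other genes fixed for naming, FGF8 stood at 0.12 at HH35, PAX5 at 0.08 and -0.09, PAX7 at -0.37 and -0.75, WNT3 at 0.16 and 0.05, RYK at 0.04 and 0.03 and RGMA at 0.28 and -1.05, none of which passed. The posterior channels of EFNB2 and FGF8 were not well above background at HH37. WNT1 was not well above background at HH35 and was not tested, and EN2 had no probe that the files pair with its symbol.

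Genes of maturing neurons were higher in the anterior pool. Taken by list, the median of the 18 measured members was -0.44 at HH35 (percentile 0.01), with 16 on the anterior side. That of 17 was -0.99 at HH37 (percentile 0), with 17 of 17 anterior, where matched random lists had a median of -0.30. The mediolateral array at HH35 also had 16 of 18 members on the Cy3 side, with a median of -0.33 (percentile 0.89). On the mediolateral array at HH30, 15 of 18 were on the Cy5 side, with a median of 0.25. Over both anteroposterior stages 6 of 18 passed limma over all genes, and 11 adjusted over the list alone. NEFL stood at -1.06 and doublecortin, DCX, at -1.05, besides NEFM and SYT1. The 9 measured glutamatergic genes had a median of -0.32 at HH35 (percentile 3.6), and 0 passed over all genes against 4 adjusted over the list alone. Cell cycle genes stood on the other side at HH35. The list had a median of 0.24 (percentile 100), with 26 of 35 members higher posteriorly and 9 anteriorly. CCNB3, at 1.25, was the 1 member past 2-fold. The proneural list stood at 0.39 (percentile 99.99), with 5 of 9 members higher posteriorly and 4 anteriorly, and at 0.0271, inside the limits of random lists, with no filter on dim probes. The neural progenitor list stood at 0.23 (percentile 98.78), with 9 of 13 higher posteriorly, and at 0.055, inside those limits, with median centring. SOX3 of that list was at 0.81. HES6, of the Notch list, was at 1.25, while the Notch list itself was at 0.03 (percentile 76.29), inside the limits. At HH37 the cell cycle list was at -0.24 (percentile 14.95) and the proneural list at -0.15 (percentile 71.7), both inside the limits. Matched random lists had medians of -0.16 and -0.24. Over both stages 0 of 35 cell cycle genes passed limma, over all genes or adjusted over the list alone. Of 8 genes tested in the proneural list, NEUROD4 was higher posteriorly and EBF3 anteriorly by limma.

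Several tectal transcription factors were higher anteriorly by limma. TFAP2B stood at -0.84, LHX9 at -0.71, GATA3 at -0.67 and MEIS2 at -0.62, making 4 of 19 in that list over all genes and 6 adjusted over the list alone. The list as a whole was at 0.0068 at HH35 (percentile 71.89), with 9 members higher posteriorly and 9 anteriorly. At HH37 it was at -0.52 (percentile 2.85, inside the limits but outside in 5 of 7 alternatives), where matched random lists had a median of -0.28. Among axon guidance genes 6 of 43 passed, all anterior, including CNTN1 at -0.99, the receptor phosphatase PTPRO at -0.89 and SEMA3D, against 7 anterior and 1 posterior adjusted over the list alone. CDH2 at -0.75 was the 1 of 22 cadherins to pass, while 10 were anterior and 1 posterior adjusted over the list alone. Of 41 Wnt pathway genes DKK3 at -0.80, LEF1 at -0.71 and WNT7B passed. FGFR3 at -0.73, FGF13 at -0.82, TGFB2 at -0.82, ALDH1A2 and VIP passed in their lists as well. No mean is given for SEMA3D, WNT7B, ALDH1A2 and VIP, whose posterior channel was not well above background at HH37. At HH35 they were at -1.44, -0.96, -2.22 and -1.24. The retinoid-related nuclear receptor RORA, at -0.99, passed from the list of isthmic, cerebellar and hindbrain markers. Markers of the ventral midbrain had a median of 0.36 at HH35 (percentile 100), with 11 of 12 higher posteriorly, and of -0.02 at HH37 (percentile 84.69). The isthmic organiser list was at 0.19 at HH35 (percentile 98.15), outside the limits in 5 of 7 alternatives, and at -0.0346 at HH37 (percentile 81.32). Medians of 6 non-neural lists at HH35 (blood, endothelium, meninges, pericytes, microglia and leukocytes, muscle and cartilage) lay between -0.11 and 0.16. The list percentiles describe these arrays and are no test across samples.

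Between HH35 and HH37 the ratio of several posterior genes was lower at the later stage. The change in log2 ratio was -2.03 for GRP, -1.95 for STMN3, and -1.93 for PNOC, with PNOC passing from 1.09 to -0.84. PAX2, at 3.0 at HH35, had a posterior channel not well above background at HH37, so no size is given for its change. In the authors' deposited table its posterior over anterior ratio was 10.32 at HH35 and 1.57 at HH37. No size is given for the change of SLC36A4, ALDH1A2, EPHA7 and CCN2, which were anterior at HH35, since their posterior channel was not well above background at HH37. For EPHA7 the authors' deposited table has an anterior over posterior ratio of 6.25 at HH35 and 5.69 at HH37. The ratio of 376 features was lower by at least 2-fold at HH37 and that of 99 higher, of 24284 measured on both arrays. In the value table the split was 1410 to 812, and with plain subtraction 712 to 420. A dye effect that is the same on both arrays cancels in this difference, whereas a dye effect that differs between them does not. With 1 array per stage it was not tested.

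The mediolateral arrays are given by channel. Their dye labels name Cy5 as medial and Cy3 as lateral, whereas the authors' deposited table, whose medial over lateral ratio runs with Cy3 over Cy5, makes Cy3 medial. The direction is therefore not settled, and no side is named for these ratios. At HH30 the Cy5 pool was higher in genes of the ventral neural tube and of the isthmus. PAX2 stood at 1.95, the somatostatin gene SST7 at 1.71, neuropeptide NPY at 1.51, NKX6-1, a homeobox gene of the ventral neural tube, at 1.49, and GRP at 1.49. The Cy3 pool was higher in TENM3, a teneurin, at -1.19, WNT3A at -1.13, the BMP antagonist NOG at -1.06 and BPIFB2 at -0.99. No size is given for PEX11A, the lowest gene by computed ratio, whose Cy5 channel was not well above background and which stood at 0.14 in the value table. In all 92 of 28100 features differed at least 2-fold, 74 higher in the Cy5 pool and 18 in the Cy3 pool. With median centring the split was 59 to 30, with plain subtraction 184 to 206, and with the values of the series' table it was 255 to 644.

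On the mediolateral array at HH35 the 5 genes with a symbol furthest to either side were as follows. WNT5A stood at -1.53, TENM3 at -1.45, CDX1 at -0.96, C1QTNF3 at -0.92 and NPY5R at -0.92, higher in the Cy3 pool. UTRN at 1.12, ADGRG6 at 0.97, PAX2 at 0.93, NTN1 at 0.87 and C11orf57 at 0.86 were higher in the Cy5 pool. The probes of UTRN ranged from -0.78 to 1.12 and those of C11orf57 from -0.18 to 0.86. Of 28418 features 27 differed at least 2-fold, 19 higher in the Cy5 pool and 8 in the Cy3 pool. In the value table the split was 259 to 453, and with plain subtraction 61 to 132.

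**Figure D2:**
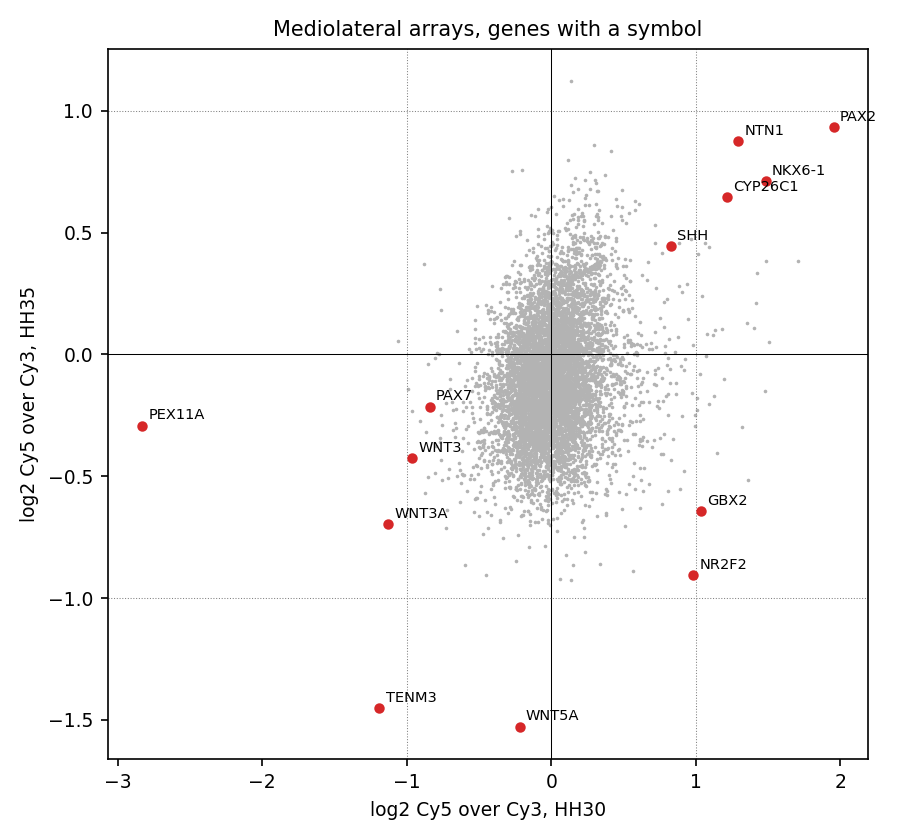
Log2 ratio of Cy5 over Cy3 on the mediolateral arrays at HH30 (x axis) and HH35 (y axis), 1 array each. Each grey point is a gene with a symbol well above background on both arrays, red points are labelled genes, and dotted lines mark a 2-fold difference. TENM3 lies at -1.19 and -1.45.

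The mediolateral ratio had the same sign at both stages for 59.4% of the 25145 features measured on both arrays. Most of the genes given here were picked for their ratio at both stages, so that their shared sign is no finding. NTN1 was at 1.30 and 0.87, NKX6-1 at 1.49 and 0.71, CYP26C1, which degrades retinoic acid, at 1.21 and 0.64, and the ventral signal SHH at 0.83 and 0.44. BSPRY, CCDC92, IL1RL1, PCDH1 and APOH also stood between 0.52 and 0.72 at both stages. Of these BSPRY, IL1RL1, PCDH1 and APOH favoured Cy5 on both anteroposterior arrays too, at 0.17 to 0.68, so a dye effect of each gene is not told from a difference along this axis. On the Cy3 side the signal WNT3A was at -1.13 and -0.69, WNT3 at -0.96 and -0.43, the hedgehog co-receptor BOC at -0.72 and -0.64, COL23A1 at -0.73 and -0.71, FGFR2 at -0.63 and -0.61, TGFB2 at -0.60 and -0.86, and the dorsal homeobox gene PAX7 at -0.84 and -0.21. RASL11AL was at -0.87 and -0.57, LHFPL1 at -0.54 and -0.65, PHF24 at -0.58 and -0.56, and BRINP2 at -0.53 and -0.59. FGFR2, TGFB2, PAX7, COL23A1, RASL11AL and LHFPL1 also favoured Cy3 on both anteroposterior arrays, at -1.02 to -0.13. Limma called 2 of 30306 features, both higher in the Cy3 pool. TENM3 had a mean of -1.32 ± 0.14 (SE, adjusted p = 0.0161), and the other was a feature without a symbol at -1.54 (adjusted p = 0.0122). At unadjusted p under 0.05 there were 2346. Both called features lay on the Cy3 side on all 4 arrays. A dye effect of either is thus not told from a difference along this axis. The anteroposterior mean reached 50% of the mediolateral mean for 0 of the 2. Limma with plain subtraction, the value table, median centring, or an intensity trend and robust variance called 0. At 2-fold, 3 features were higher in the Cy3 pool at both stages and 1 in the Cy5 pool, where independent lists would share 0.005 and 0.026, and TENM3 was the 1 of these 4 with a symbol. In the value table the shared features were 30 and 17. Without the HH35 array limma called 20, without either anteroposterior array 18, and without the HH30 array 1.

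Several gene lists stood apart from matched random lists on the mediolateral array at HH30. Markers of the ventral midbrain had a median of 0.45 (percentile 100), with 10 of 11 members higher in the Cy5 pool. The list fixed for pretectum and thalamus stood at 0.45 (percentile 100), with 9 of 15 members higher in the Cy5 pool and 6 in the Cy3 pool. SIX3 at 1.42, PAX6 at 1.40 and NKX2-1 at 1.08 were among its members. With this split, the median does not show that the Cy5 pool held pretectal or thalamic tissue. The isthmic organiser list stood at 0.38 (percentile 100). Maturing neuron genes were at 0.25 (percentile 99.98), with SYT4 at 1.12. On the Cy3 side were the proneural list at -0.33 (percentile 0), EphB receptors at -0.53 (percentile 0), with EPHB2 at -0.66 and EPHB3 at -0.65, the tectal transcription factor list at -0.27 (percentile 0), cell cycle genes at -0.14 (percentile 0.05) and markers of the meninges at -0.25 (percentile 0). At HH35 the ventral midbrain list was at 0.06 (percentile 95.87) and the maturing neuron list at -0.33 (percentile 0.89, outside the limits in 5 of 7 alternatives). Over both stages 0 members of these lists passed limma over all genes. Adjusted over the list alone, the hedgehog list had 6 higher in the Cy5 pool and 1 in the Cy3 pool of 14. The Wnt list had 5 of 41 higher in the Cy3 pool.

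**Figure D3:**
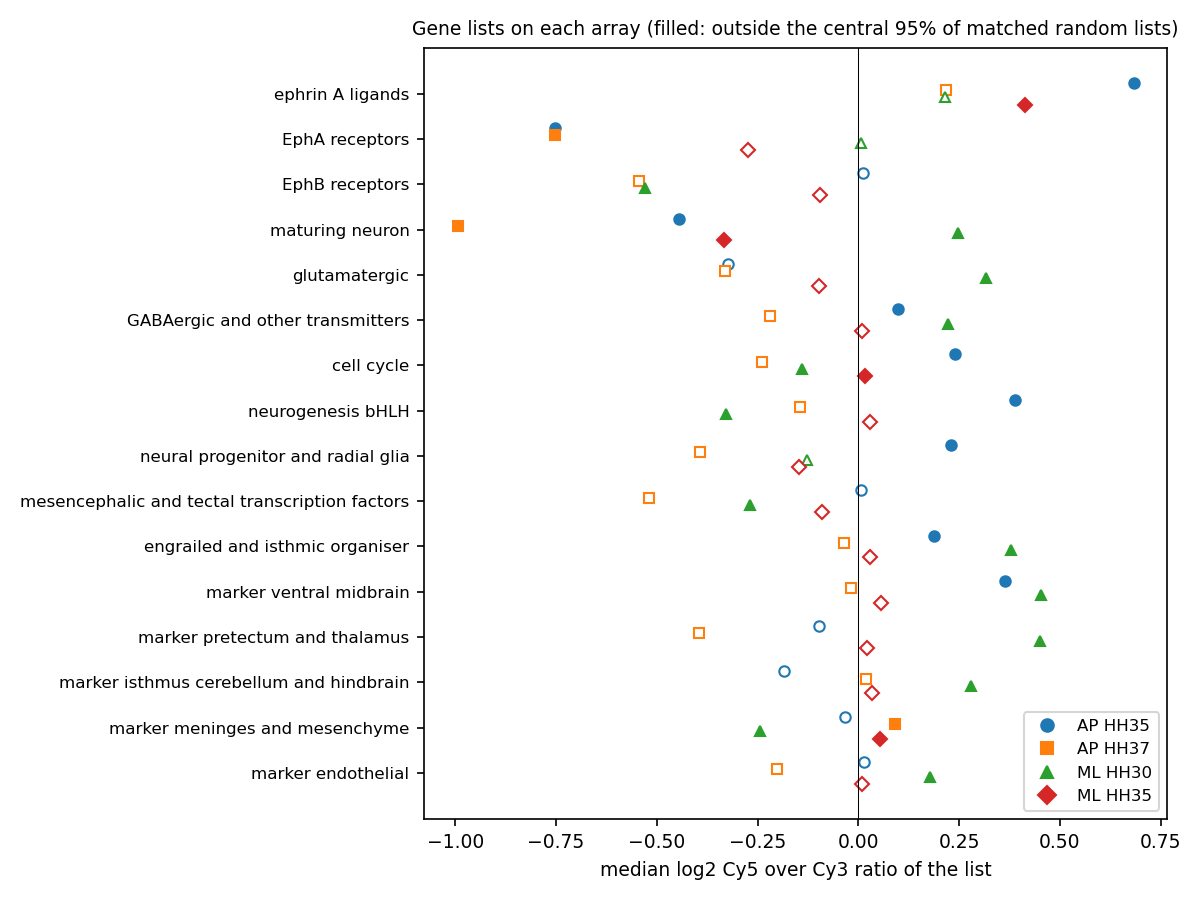
Median log2 Cy5 over Cy3 ratio (x axis) of 16 gene lists (y axis) on each of the 4 arrays, marked by shape and colour. Filled symbols lie in the outer 2.5% at either end of 10000 random lists matched on brightness. The maturing neuron list lies at -0.44, -0.99, 0.25 and -0.33.

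From HH30 to HH35 the change in the mediolateral log2 ratio was -1.89 for NR2F2, -1.68 for GBX2 and -1.63 for GABRQ. It was 1.25 for MSX2 and 1.11 for NOG. No size is given for PEX11A, whose Cy5 channel was not well above background at either stage. The ratio of 119 features was lower by at least 2-fold and that of 26 higher, of 25145 measured on both arrays, with no test. In the value table the split was 627 to 672, and with plain subtraction 350 to 246.

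The contrast of the axes, anteroposterior minus mediolateral, removes a dye effect that a gene shows on all arrays. Limma called 0 of 30306 features in it. EPHA3 had an adjusted p of 0.273 there, NEFM of 0.273 and ELMOD1 of 0.273. At unadjusted p under 0.05 there were 2503, of which 1787 were lower, and with an intensity trend and robust variance 1 passed, LOC419390. Leaving out 1 array gave 0 to 41, with 17 without the anteroposterior array at HH35, 41 without that at HH37, 38 without the mediolateral array at HH35 and 0 without that at HH30. With all 4 arrays and adjustment over the list alone, the contrast was lower for 4 of 5 EphA receptors, 8 of 18 maturing neuron genes and 4 of 9 glutamatergic genes. Every other list had at most 2 called either way. A dye effect that differs between arrays stays in the contrast. Across 22343 genes and features measured on all arrays, which are not independent replicates, the ratios at the 2 anteroposterior stages correlated with r = 0.443 and those at the 2 mediolateral stages with r = 0.26. The mediolateral array at HH35 correlated with the anteroposterior array at HH37 with r = 0.633 and with that at HH35 with r = 0.381. The correlation between the mediolateral array at HH30 and the anteroposterior array at HH35 was 0.15, and that between HH37 and the mediolateral array at HH30 was 0.02.

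In the authors' deposited table the anterior over posterior ratio at HH35 was 7.12 for EPHA3, 6.25 for EPHA7 and 0.201 for EN1. In the same authors' deposited table the ratio it calls medial over lateral was 2.04 for WNT3 and 0.518 for SHH at HH30. Of 41824 probes in the authors' deposited table, 878 were at least 2-fold up and 574 down in the anterior pool at HH35, and 2885 up and 2780 down at HH37. For the pool it calls medial, the authors' deposited table had 939 up and 1254 down at HH30, and 732 up and 1027 down at HH35.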

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

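All tests reported in this part were chosen after the results they bear on were seen, except that of the slide surface, whose outcome was stated beforehand. The 1.5-fold limit for genes with opposite signs at both stages was also chosen after the data were seen.

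A difference between stages was marked for 4 genes and 3 gene lists that stood on opposite sides at the earlier and the later stage, and in no case was the difference tested. The anteroposterior log2 ratio of PNOC, the precursor of nociceptin, went from 1.09 at HH35 to -0.84 at HH37, a difference of -1.93 that was not tested. SOX8 went from 0.67 to -0.64 on the same axis, a difference of -1.31. The mediolateral ratio of NR2F2 went from 0.98 at HH30 to -0.91 at HH35, a difference of -1.89. GBX2 went from 1.04 to -0.64 on that axis, a difference of -1.68. The median of the cell cycle list went from -0.14 to 0.02 on the mediolateral arrays, a difference of 0.16, and the later value turned to -0.09 with median centring. The maturing neuron list went from 0.25 to -0.33 there, a difference of -0.58, the later value lying outside the limits of random lists in 5 of 7 alternatives. Markers of meninges and mesenchyme went from -0.25 to 0.05, a difference of 0.30, with a later value of -0.0001 under median centring.

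The dye labels and the authors' deposited table name opposite channels as medial on both mediolateral arrays. Markers of the ventral midbrain, which adjoins the lateral side of the tectum, had a median of 0.45 in favour of Cy5 at HH30 (0.06 at HH35), which is what a reversal of the dye labels would give. That median was at percentile 100 of matched random lists at HH30 (95.87 at HH35), the same evidence read against a reversal in the table. The list leaned to Cy5 on the anteroposterior array at HH35 too, at 0.36 (percentile 100). In the contrast of the axes its median was -0.0295, with 0 members called. A lean to Cy5 is thus not particular to the mediolateral arrays and cannot by itself decide between labels and table. That Cy5 held the lateral pool remains a candidate explanation, a hypothesis found and tested on the same arrays.

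The ratios of the anteroposterior array at HH37 and the mediolateral array at HH35, which share no axis, correlated across genes with r = 0.633, above the r = 0.443 of both anteroposterior stages, and the anteroposterior array at HH35 correlated with that mediolateral array with r = 0.381, above the 0.26 of both mediolateral stages. A dye effect that each gene shows alike on all arrays is, as the whole cause, argued against by the lowest correlation between arrays, 0.02. A brightness trend left by loess is argued against by correlations of at least 0.49 within 3 groups of genes by brightness, and a trend over the slide surface by a correlation of 0.635 after the local median was subtracted. A dye effect that differs between hybridisations was not tested and stays open, as does a difference in the tissue itself. While it is open, part of the anterior excess at HH35 and HH37 may belong to neither axis. Mean ratios of repeated control spots bear on such a dye effect without deciding it. On this pair E1A_r60_a20 was at 0.36 and 0.20, against 0.03 and -0.14 on the anteroposterior HH35 and mediolateral HH30 arrays. E1A_r60_a22 was at 0.08 and 0.05, against -0.24 and -0.12. The pair differed for E1A_r60_a104, at 0.24 and 0.01, against 0.14 and -0.09. ETG10_234183 was at 0.19 and 0.29, against 0.53 and 0.12. The control eQC-40 was at 0.55 and 0.53 on this pair and had too few bright spots on the others.

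Genes of maturing neurons were higher in the anterior pool at both stages. A dye effect common to all arrays is argued against by the list's median of 0.25 on the mediolateral array at HH30 (percentile 99.98), and a lower share of neural tissue in the posterior pool at HH35 by the highest median of 6 non-neural lists, 0.16 (the lowest was -0.11). At HH37, where the neuronal median was -0.99, those lists lay between -0.20 and 0.09, with meninges highest (percentile 99.34, outside the limits in 3 of 7 alternatives) and choroid plexus, outside the 6, at 0.24 (percentile 99.28, in 5 of 7), so a contribution of other tissue stays open there. Fewer differentiated neurons with more dividing cells posteriorly may account for HH35, where the cell cycle list was at percentile 100, but at HH37 it was at 14.95, or between 1.78 in the value table, below the limit of 2.5, and 42.95 with both channels above background, so the data do not decide. Also open are the likeness of both anteroposterior arrays to the mediolateral array at HH35, where the neuronal list stood at -0.33 (outside the limits in 5 of 7 alternatives), and, as an untested biological explanation, a difference in maturation between the pools.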

How the results depend on the processing

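The filter on negative controls, the filter on the signal-to-noise score and the median of spot pixels were chosen after the data were seen. Counts of features at least 2-fold apart are given in the order anteroposterior HH35, HH37, mediolateral HH30, HH35, shared by both stages on either axis, and changed with stage on either axis, and were 250, 475, 92, 27, 14, 4, 475 and 145. With plain background subtraction they were 677, 1074, 390, 193, 61, 14, 1132 and 596. In the value table they were 1067, 2236, 899, 712, 135, 47, 2222 and 1299. At 1.5-fold they were 2578, 2896, 750, 630, 523, 55, 3144 and 1473. Median centring gave 700 and 1906 on the anteroposterior arrays, 132 shared and 906 changed with stage. With the other axis subtracted as a dye estimate the mediolateral arrays gave 510 and 65, and 39 and 26 were shared on the anteroposterior and mediolateral axes. The median of spot pixels gave 22 shared on the anteroposterior axis. The cause was not tested.

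The limma count of 833 on the anteroposterior axis was 0 with plain subtraction (6067 at unadjusted p under 0.05), 0 in the value table (5400), 1 with trend and robust variance (6906), 4290 with median centring, 1265 with both channels above background, 441 with no filter, 233 with array weights and 2717 at adjusted p under 0.1. Leaving out 1 array gave 676 to 1470. The mediolateral count of 2 was 0 with plain subtraction (2040), 0 with median centring (2207), 0 in the value table (1969), 0 with trend and robust variance (2181) and 5 with array weights, and 1 to 20 with 1 array left out. The contrast of the axes went from 0 to 1 with trend and robust variance, and to 0 to 41 with 1 array left out. The lone array of an axis is then assumed to vary like the others. Of 38 named genes called on the anteroposterior axis, all 38 kept their sign in each limma setting run, which their selection on the same arrays made likely. Called again were 0 with plain subtraction, the value table, or trend and robust variance, 14 with array weights, 19 without the array at HH37 and 20 with no filter.

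PHC1 at HH37 turned to -0.69 in the value table and -0.43 with the median of spot pixels, and SNRNP40 to -0.32 and -0.12. PEX11A turned to 0.14 in the value table at HH30, and UTRN to -0.0435 with the mean of its probes at HH35. Of 136 list medians, 31 changed sign with median centring and 14 in the value table, 12 and 3 of them on the anteroposterior array at HH35. Most lay inside the limits of random lists, and among the 47 outside them 7 changed sign with median centring and 1 in the value table. These are given next. With median centring the anteroposterior medians of the hedgehog list (-0.0043) and the GABAergic list (-0.0242) turned at HH35, and those of meninges (-0.11), choroid plexus (-0.0737) and eye (-0.0440) at HH37. On the mediolateral array at HH35 it turned the cell cycle list (-0.0928) and meninges (-0.0001). The value table turned the cell cycle list to -0.0960 there. The mean of probes turned blood markers to -0.0645 there and meninges to -0.0256 at HH37, and no filter turned meninges to -0.0277. Of the other values of single genes and lists over all alternatives, 8351 and 803 moved by no more than the spread taken for them and 1275 and 136 by more, changes of sign of genes under 2-fold and of lists inside the limits counted with these. Of the axis coefficients 7591 stayed on their side of the threshold, and 134 coefficients passed and 215 lost the threshold.

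Alternatives planned on Feature Extraction's processed signals and on its p-value were not run, since the files hold no such columns. No paired analysis was possible because each group is 1 array. Signal over background limits the array at HH37 most, with 41.2% of probes above background in Cy5.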

Other observations

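Several groups outside the main comparisons stood apart from matched random lists on single arrays, as values with no test. Genes of GABAergic and other transmitter systems had a median of 0.22 in favour of Cy5 on the mediolateral array at HH30 (percentile 100), and glutamatergic genes of 0.32 (percentile 99.88). FGF ligands and receptors stood at -0.53 on the anteroposterior array at HH37 (percentile 0.2), outside the limits in 5 of 7 alternatives with medians from -0.84 to -0.24, and axon guidance genes at -0.39 (percentile 2.02), outside in 6 of 7. BMP and TGF-beta genes stood at -0.13 on the mediolateral array at HH30 (percentile 0.16). Hedgehog genes were at 0.19 there (percentile 99.61) and markers of isthmus, cerebellum and hindbrain at 0.28 (percentile 99.97).

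Markers of the oligodendrocyte lineage had a median of 0.29 at HH35 on the anteroposterior axis (percentile 99.74). Astroglial markers stood at 0.48 on the mediolateral array at HH30 (percentile 99.92), endothelial markers at 0.18 (percentile 99.7) and markers of choroid plexus and ependyma at 0.26 (percentile 99.79). Eye markers stood at 0.11 at HH35 and 0.12 at HH37 on the anteroposterior axis (percentiles 98.14 and 98.06), outside in 5 and 6 of 7 alternatives, the latter turning to -0.0440 with median centring. Retinoic acid genes, at 0.10, Notch genes, at 0.03, stress genes, at 0.0024, and ribosomal protein genes, at 0.0026, lay inside the limits at HH35 on that axis. Microglial markers, at 0.12, and muscle and cartilage markers, at 0.11, lay above them on the mediolateral array at HH35 (percentiles 99.48 and 99.69), in 7 and 6 of 7 alternatives.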
